A study of Mus musculus with 23 samples.

How the data were processed

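The samples were total RNA from ventricles of 23 male mice, prepared with RNeasy kits and checked on a Bioanalyzer per the labels' protocols. Each was labelled with Cy5 and hybridised against a Cy3-labelled pool of liver, brain, heart, kidney and spleen RNA on a 2-colour Agilent array, per the labels. All arrays had the same dye orientation. Arrays were read with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. Genotype, treatment and sample number were taken from the sample labels, and each array was treated as 1 mouse. Mice are named here by their sample number within the group.

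The deposited values are log2 ratios of heart over reference, 1 per probe and array. The dyes come from the labels. The base and the sign were inferred from the values: the spike-in control probes span the range that base 2 gives, ratios reach −12.71 and 8.80, heart genes lie above 0 and brain genes below 0. The background correction and within-array normalization behind these ratios are not given in the sources used here, and single-channel signals and signal over background were not used here. The value table held 39485 lines with 0 missing values and 0 values of exactly 0. After removal of 56 control probes, 39429 probes remained. The array annotation gave 1 gene symbol for 30625 probes and several for 0, and 8804 probes were unnamed here. Probes of a gene were averaged, which gave 21892 genes, 15085 of them with 1 probe. Gene identifiers of 30331 probes were found in a reference gene table, and 0 symbols needed an update. No genome build is named for these values, so no coordinates are given. All columns of the table belonged to the 23 samples.

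Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit on the log2 ratios of all 23 arrays, 1 mean per group, and eBayes with default settings. Tests were two-sided with Benjamini-Hochberg adjustment over 21892 genes and a threshold of 0.05. No further normalization between arrays was applied. The comparisons were untreated MR-Cardio against untreated controls, aldosterone against none in each genotype, MR-Cardio against controls under aldosterone, and the interaction. The first 3 are those the series design names. Values are given as the log2 difference with its standard error, or as group mean with SD, and folds are powers of 2 of the log2 difference. Because mice of 1 genotype and treatment are separate animals, p-values of genes refer to the spread between animals, pooled over all groups. Those of camera, described next, also depend on the correlation between genes that is assumed.

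Gene lists, 17 of pathways and 15 of cell type markers, held 624 genes, of which 578 were measured. Older names were matched only where no other current gene bears the name. They were compared with all other genes by limma's camera with its preset inter-gene correlation of 0.01, adjusted over the 32 lists. The correlation estimated from the data ran from 0.001 to 0.777 over the lists. It was 0.579 for cell cycle, 0.593 for matrix and 0.777 for oxidative phosphorylation genes. For lists whose genes move together in this way, camera's p-values with the preset are too small. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance, were run as alternatives. Calls within a list were also adjusted over the list alone. The mean ratio of a list in each mouse was tested between groups with an exact permutation test (scipy 1.17.1, two-sided). Correlations of effects across genes are Pearson's r and Spearman's rho, with a jackknife over mice.

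The gene lists, the tests, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took, for each comparison, the 12 largest rises and 12 largest falls past the threshold, leaving out clone and predicted names, or the 10 smallest p-values where fewer than 10 genes passed. The 5 smallest p-values stood for the interaction. To these came list members past the threshold, 2 to 4 examples per list by smallest p, and 17 genes of receptor action, hypertrophy and fibrosis. Scaling by the spike-in slope, the spike-in offset as a covariate, restriction to genes with a mean ratio over 0 and the list scores per mouse were added after the data had been seen.

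The alternatives were centring each array on its median, quantile normalization, the most variable probe per gene, each probe on its own, the compared groups alone, trend and robust eBayes, array quality weights, leaving out genes with the lowest mean ratios so that 16419 were tested, the sample number as a block, each mouse left out in turn and other thresholds. The sample numbers recur across groups, while each mouse has an animal number of its own in the labels, so nothing in them ties mice of the same sample number. For each result fitted across genes, 100 assignments of the mice to groups of the same sizes, the real one included, were fitted again. The limma step was tested on simulated data of 21892 genes in which 67, 67 and 66 genes were changed by 0.5, 1 and 2 log2 units. Noise was drawn independently for each gene, with the same SD in all groups. Correlation between genes and unequal spread of the groups were thus left out, and the shares below apply to that setting alone. For untreated MR-Cardio against controls it recovered 40.3% of changes of 0.5 log2 units, 68.7% of those of 1 and 98.5% of those of 2. For aldosterone in controls the shares were 43.3%, 82.1% and 93.9%, and in MR-Cardio mice 41.8%, 82.1% and 98.5%. Under aldosterone the genotype comparison recovered 43.3%, 79.1% and 100%, and the interaction 20.9%, 55.2% and 87.9%. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.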

Results

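Gene expression was measured in ventricles of 23 male mice, 1 mouse per array, on 2-colour arrays that gave the log2 ratio of heart RNA over a common reference. The reference was RNA pooled from liver, brain, heart, kidney and spleen. MR-Cardio mice overexpress the mineralocorticoid receptor, the nuclear receptor that binds aldosterone, in cardiomyocytes, and the controls were non-transgenic. The groups were untreated controls (n = 5), controls given aldosterone (n = 5), untreated MR-Cardio mice (n = 7) and MR-Cardio mice given aldosterone (n = 6), with a duration of 7 days. The question set by the design was which cardiac genes aldosterone regulates in each genotype and which genes the receptor itself changes. Ratios were available for 21892 named genes on every array. Array medians lay between −0.04 and 0.12, and the lowest correlation between 2 arrays over all probes was 0.855. The number of arrays limits the precision of each value.

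Untreated MR-Cardio hearts carried 6.86-fold more Nr3c2, the mineralocorticoid receptor gene, than untreated controls. Its log2 ratio was 3.21 ± 0.72 (SD, n = 7) against 0.43 ± 0.14 (SD, n = 5), a difference of 2.78 ± 0.34 (SE, adjusted p = 8.84e-06), and each MR-Cardio heart lay above each control. Fkbp5, a co-chaperone of steroid receptors that corticosteroids induce, rose 8.60-fold, from −0.05 ± 0.12 (SD, n = 5) to 3.06 ± 0.55 (SD, n = 7). Cited1, a transcriptional coactivator, rose 38.7-fold (5.27 ± 0.32, adjusted p = 7.45e-10), from −0.15 ± 0.61 (SD, n = 5) to 5.12 ± 0.68 (SD, n = 7). Lcn2, which encodes the secreted protein lipocalin 2, rose by 1.93 ± 0.22 (SE), and Serpina3n, a serine protease inhibitor of the acute phase, rose by 1.78 ± 0.42 (adjusted p = 0.00663).

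In all, 2978 of 21892 genes (13.6%) differed between untreated MR-Cardio and control hearts, 1267 higher and 1711 lower, and 499 of them differed by 1 log2 unit or more. Among the largest rises, Ffar4, a receptor for long-chain fatty acids, rose 34.7-fold, and Kcnk1, a background potassium channel, rose 30.9-fold. Amy1, which encodes salivary amylase, rose 29.7-fold from a mean log2 ratio of −4.26 in untreated controls. Mthfd2, a mitochondrial enzyme of folate metabolism, rose 18.2-fold. The fast skeletal muscle troponins Tnnt3 and Tnni2 rose by 4.17 ± 0.48 and 3.84 ± 0.37 (SE, log2). Klk1b16, a kallikrein, rose by 5.62 ± 1.09 (SE, log2), Nrl by 4.26 ± 0.29, Slc25a18 by 4.63, Plpp4 by 4.12 and Mlph by 3.75. An outlying Klk1b16 ratio of −4.23 in control 1, against a mean of −0.01 over the untreated controls, enlarges the first of these rises. The largest falls were those of Meig1 (−3.19 ± 0.76), Eprn (−2.78 ± 0.56), Apof (−2.44 ± 0.13), which encodes an apolipoprotein made in liver, and Scn4b (−2.39 ± 0.62), a sodium channel subunit. Sun3 (−2.17 ± 0.52), Dner (−2.10 ± 0.25), a neuronal Notch ligand, Tspan10 (−1.99) and Gad1 (−1.93 ± 0.31), an enzyme of GABA synthesis, also fell, as did Lgi1 (−1.93), Prss55 (−1.90), Defb19 (−1.84) and the clone D4Ertd617e (−1.96). With the compared pair of groups alone in the fit, the calls of Scn4b, Lgi1, Prss55 and Defb19 were lost; that of Lgi1 was also lost without control 4, that of Prss55 without control 2 and that of Defb19 without control 1 or 2.

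Of the genes fixed in advance as markers of receptor action, hypertrophy and fibrosis, Myh7, the fetal isoform of the cardiac myosin heavy chain, rose by 1.89 ± 0.50 (SE, adjusted p = 0.0146), a call lost with the pair of groups alone. Sgk1, a kinase that aldosterone induces in kidney, had a difference of −0.07 ± 0.16 (adjusted p = 0.836). Tsc22d3, another corticosteroid target, differed by 0.34 ± 0.17 (adjusted p = 0.193), Per1 by 0.04, Zbtb16 by 0.09, Hsd11b2, which inactivates glucocorticoids, by −0.17 and Nr3c1, the glucocorticoid receptor, by −0.00 (adjusted p = 0.977), and none of these passed. The natriuretic peptide genes Nppa (0.90 ± 0.35, adjusted p = 0.0929) and Nppb (1.05 ± 0.54, adjusted p = 0.213) did not pass either, nor did Myh6 (−0.11). Differences of Col1a1 (1.40 ± 0.59), Col3a1 (1.41 ± 0.56) and Ccn2 (1.38 ± 0.55), genes of collagen and of a matrix growth factor, had adjusted p = 0.121, 0.0970 and 0.0973. These 3 genes passed with array quality weights, Col3a1 and Ccn2 also without MR-Cardio mouse 6, Ccn2 without MR-Cardio mouse 2, Nppa without control 2 and Nppb without MR-Cardio mouse 6.

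**Figure D1:**
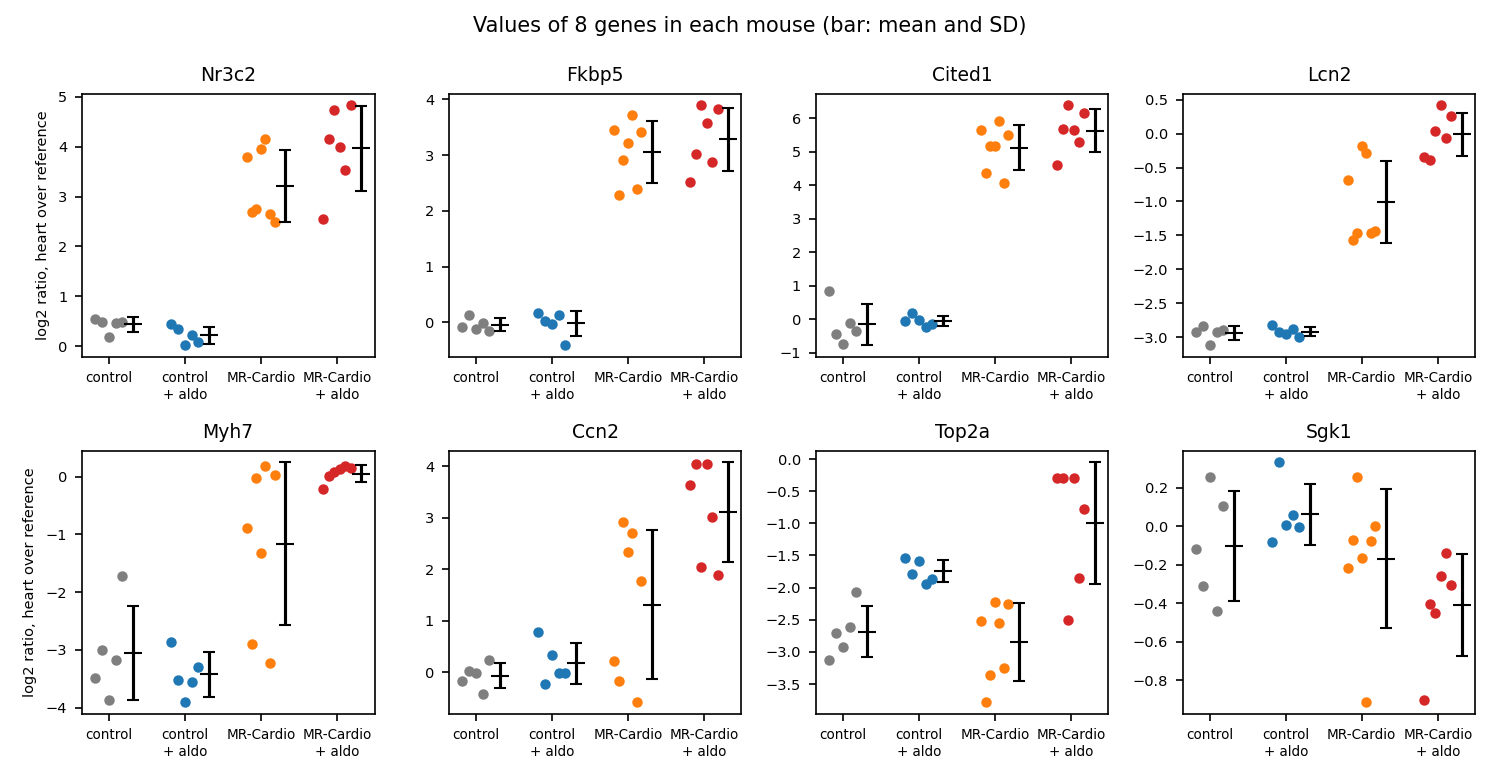
Log2 ratio of heart over reference for 8 genes in each of the 23 mice, with points for mice and bars for the group mean and SD. Nr3c2 averages 3.21 in untreated MR-Cardio hearts against 0.43 in untreated controls, and Ccn2 and Myh7 vary widely between untreated MR-Cardio mice.

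Among 34 measured corticosteroid-responsive genes, 13 rose, 2 fell and 19 did not pass in untreated MR-Cardio hearts, and 14 rose and 2 fell when adjusted over the list alone. The list shifted upward by a median of 0.33 log2 units (camera adjusted p = 9.79e-05, adjusted p = 0.383 with an estimated correlation). Besides Fkbp5 and Lcn2, the sulfotransferase Sult1a1 rose by 1.72 ± 0.25, while Orm1, an acute-phase protein of liver, fell by 1.21 on the log2 scale. The mean ratio of the list in each mouse was −0.14 ± 0.11 (SD, n = 7) against −0.66 ± 0.14 (SD, n = 5), with 7 of 7 MR-Cardio hearts above every control (exact permutation p = 0.00253, adjusted p = 0.0202).

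Camera called the matrix and inflammation lists higher in untreated MR-Cardio hearts. Of 33 matrix and fibrosis genes 10 rose, 0 fell and 23 did not pass (19 rose and 1 fell adjusted over the list alone), with a median of 0.89 (camera adjusted p = 5.87e-09, adjusted p = 0.436 with an estimated correlation). Lox, which cross-links collagen, rose 7.73-fold (2.95 ± 0.42, SE), Timp1, an inhibitor of matrix proteases, rose by 2.14 ± 0.52 and Tgfbr1, a receptor of transforming growth factor beta, by 0.87 ± 0.18. Of 22 inflammation genes 7 rose, 0 fell and 15 did not pass (10 and 0 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 9.41e-06, adjusted p = 0.383 with an estimated correlation). The scores of extracellular matrix and fibrosis lay above every control in 4 of 7 MR-Cardio hearts (1.35 to 2.03) and within the control range in the other 3 (0.34 to 0.53, adjusted p = 0.0449), and those of inflammation lay above in 6 of 7 (adjusted p = 0.0346). The spike-in offset is an array's mean spike-in ratio relative to all arrays. Of the 4 hearts with high matrix scores, mice 3, 4 and 7 had offsets of −0.38, −0.50 and −0.34. Mouse 5 (matrix score 1.35) had 0.23, and the 3 hearts within the control range had 0.17 to 0.28. The split of matrix scores is therefore not fully separable from this array difference. Examples of inflammation genes were the pentraxin Ptx3 (2.51 ± 0.45), the adhesion molecule Vcam1 (0.98 ± 0.20) and the interleukin 6 receptor Il6ra (0.60 ± 0.12). Of 14 fibroblast markers 5 rose, 0 fell and 9 did not pass (7 and 0 adjusted over the list alone), among them Mfap5 (1.14 ± 0.26), Dpt (0.65 ± 0.15) and Pdgfra (0.68 ± 0.16), with a median of 0.46 (camera adjusted p = 9.79e-05, adjusted p = 0.383 with an estimated correlation). None of 14 macrophage markers passed (0 rose and 0 fell adjusted over the list alone), and their median of 0.40 was called by camera (adjusted p = 0.00932, adjusted p = 0.623 with an estimated correlation), a call lost without control 4. The macrophage markers did not pass in scores per mouse (adjusted p = 0.242) or in fry (adjusted p = 0.174).

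Camera also called the hypertrophy and immediate early lists higher, and the fatty acid oxidation and oxidative phosphorylation lists lower, in untreated MR-Cardio hearts. The scores of these 4 lists per mouse did not pass (adjusted p = 0.0566 to 0.199), and fry did not call the last 2 (adjusted p = 0.174 and 0.248). MR-Cardio mice 3, 4, 5 and 7, with high matrix scores, exceeded every control for hypertrophy genes (1.76 to 2.39 against at most 1.44). So did their immediate early scores (0.53 to 0.88 against at most 0.13). Their fatty acid oxidation scores (0.71 to 1.09) lay below every control (1.13 or more). For oxidative phosphorylation only mice 3 and 4 did. Mice 1, 2 and 6 lay in or near the control range for all 4. These shifts are thus not separable from the split of matrix scores. Of 22 genes of hypertrophy and the fetal program 6 rose, 0 fell and 16 did not pass (6 and 0 adjusted over the list alone), among them the sarcomere protein Xirp1 (0.63 ± 0.14, SE) and the cardiac transcription factor Hand2 (0.67 ± 0.16), with a median of 0.29 (camera adjusted p = 0.000828, adjusted p = 0.436 with an estimated correlation). Of 23 immediate early genes 4 rose, 0 fell and 19 did not pass (6 and 0 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.000222, adjusted p = 0.383 with an estimated correlation). The transcription factors Egr2 (1.81 ± 0.49, lost without control 4) and Nr4a1 (1.43 ± 0.39, lost with the pair of groups alone) were among them. Of 29 fatty acid oxidation genes 1 rose, 3 fell and 25 did not pass (1 and 5 adjusted over the list alone), with a median of −0.26 (camera adjusted p = 0.00932, adjusted p = 0.686 with an estimated correlation), a call lost without control 2. The thioesterase Acot2 (−0.86 ± 0.22) and the thiolase Acaa2 (−0.50 ± 0.13) fell, while Plin5, which coats lipid droplets, rose by 0.72 ± 0.21. Of 37 oxidative phosphorylation genes 1 rose, 5 fell and 31 did not pass (1 and 5 adjusted over the list alone), among them Ndufs3 of complex I (−0.49 ± 0.11) and the ATP synthase subunit Atp5a1 (−0.53 ± 0.12), with a median of −0.16 (camera adjusted p = 0.00408, adjusted p = 0.723 with an estimated correlation). Of 22 heat shock and unfolded protein response genes 0 rose, 7 fell and 15 did not pass (0 and 7 adjusted over the list alone), including the mitochondrial chaperonins Hspe1 (−0.54 ± 0.10) and Hspd1 (−0.51 ± 0.13), with a median of −0.22 (camera adjusted p = 0.0442, adjusted p = 0.383 with an estimated correlation). That last list call was lost in 7 of the 12 fits that left out 1 mouse.

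Markers of liver, a tissue in the reference pool, were lower in all untreated MR-Cardio hearts. All 10 measured liver markers fell (0 rose and 10 fell adjusted over the list alone), including Fga (−1.64 ± 0.13, SE), Serpina1a (−1.05 ± 0.08) and Apoa1 (−0.97 ± 0.09), with a median of −0.92 (camera adjusted p = 1.92e-16, adjusted p = 0.0654 with an estimated correlation). Their mean ratio was −4.51 ± 0.14 (SD, n = 7) against −3.62 ± 0.08 (SD, n = 5). Of 7 erythroid markers 4 fell, 0 rose and 3 did not pass (0 rose and 5 fell adjusted over the list alone), with a median of −0.39 (camera adjusted p = 0.00314, adjusted p = 0.383 with an estimated correlation). Slc4a1, the red cell anion exchanger, fell by 0.39 on the log2 scale and stood at 0.00 after quantile normalization between arrays. The slope of 10 spike-in control probes, which measures how wide an array's ratios are, moved with genotype in the same way. Relative to the mean of all arrays, it was 0.964 to 0.982 on the arrays of the 10 control mice and 1.003 to 1.029 on those of the 13 MR-Cardio mice. The untreated groups differed by 0.0479 (exact permutation p = 0.00253), and a difference between arrays that follows genotype cannot be told apart from genotype in these samples. Genes of the other reference tissues were lower too, with medians of −0.34 for brain, −0.34 for kidney and −0.32 for spleen and blood. Falls of genes such as Dner, Gad1, Lgi1 and the erythroid markers are therefore not separable from this array difference. The gene groups called between genotypes differ between the same arrays as this slope and the liver markers. Mouse by mouse the matrix scores did not follow the slope. Untreated MR-Cardio mice 1, 2 and 6 had slopes of 1.028, 1.024 and 1.017, while their matrix scores of 0.53, 0.36 and 0.34 lay within the control range. With each array divided by its slope 3157 genes passed, and of the named genes 107 kept their side of the threshold and 16 lost their call. All 32 lists, the liver markers among them, kept their side of the threshold with this scaling. It changes only the width of the ratios, so it cannot exclude other array differences between genotypes. Of 100 assignments of these mice, the real one included, 5 gave as many list calls.

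**Figure D2:**
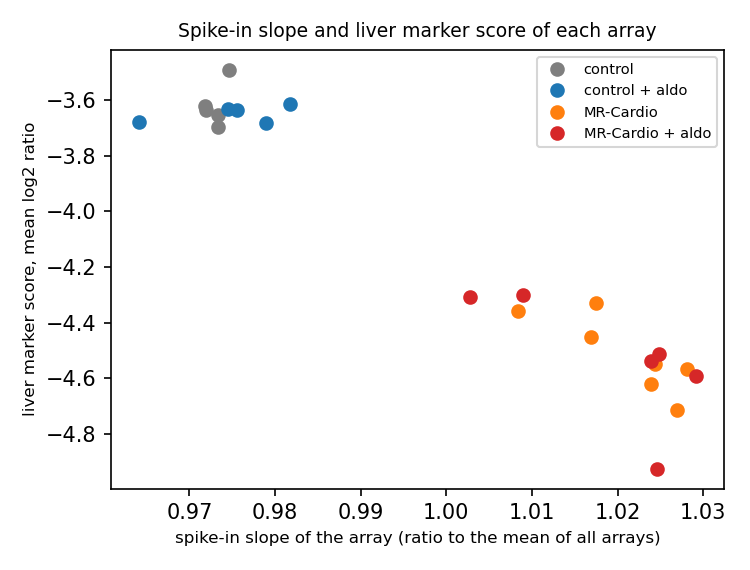
Mean log2 ratio of the liver markers on each array (vertical) against the array's spike-in slope, as a ratio to the mean of all arrays (horizontal), with 1 point per mouse. Arrays of the 10 control mice lie between 0.964 and 0.982 and those of the 13 MR-Cardio mice between 1.003 and 1.029.

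Camera did not call the other 20 lists between untreated genotypes. Fry called 16 of the 32 lists, 7 of them among these 20: oxidative stress genes and mural cell, lymphocyte, adipocyte, brown adipocyte, atrial and skeletal muscle markers. The scores per mouse passed for 9 lists, 2 of them among these 20: adipocyte markers, lower by 0.45 on the log2 scale (adjusted p = 0.0346), and skeletal muscle markers, higher by 0.59 with 7 of 7 hearts above every control (adjusted p = 0.0202). Of 34 ion channel and calcium handling genes 4 rose and 6 fell (5 and 6 adjusted over the list alone), among them Fkbp1b, a ryanodine receptor partner (0.93 ± 0.18, SE), and the potassium channel Kcnd2 (−0.70 ± 0.19). Of 24 oxidative stress genes 1 rose and 4 fell, including the glutathione peroxidase Gpx3 (−1.02 ± 0.21), with a median of −0.14 (camera adjusted p = 0.153). Of 17 genes of the mineralocorticoid and renin-angiotensin axis 2 rose and 1, the angiotensin(1-7) receptor Mas1 (−1.58 ± 0.35), fell. Of 21 glycolysis genes 4 rose, including Pgk1 (0.42 ± 0.09) and Hk1 (0.41 ± 0.09), and 1 fell. Of 10 atrial markers 5 fell and 0 rose (5 fell and 2 rose adjusted over the list alone), including the falls of Myl7 (−0.94 ± 0.15) and Sln (−0.76 ± 0.13), with a median of −0.23 (camera adjusted p = 0.192). Of 12 skeletal muscle markers 3 rose, Tnnt3 and Tnni2 among them, and 2 fell, with a median of −0.10. Medians were 0.03 for circadian clock genes, −0.33 for interferon response genes, 0.12 for cell cycle genes, 0.03 for ribosomal protein genes and −0.04 for protein breakdown genes. The score difference of the interferon response list shrank from −0.27 to −0.05 without control 2. Among marker lists they were 0.06 for cardiomyocytes, −0.07 for endothelium, 0.20 for mural cells, −0.12 for neutrophils, −0.23 for lymphocytes and −0.02 for brown adipocytes. Adipocytes (−0.40), glia (−0.04) and mesothelium (−0.09) completed the lists.

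Aldosterone for 7 days was followed by higher cell cycle genes in control hearts by point values, while no single gene passed in the fit of all groups. Of 24 cell cycle genes 21 were higher, with a median of 0.70, 0 passed over all genes and 15 rose adjusted over the list alone (camera adjusted p = 1.40e-20, adjusted p = 0.275 with an estimated correlation). Their mean ratio was −1.24 ± 0.05 (SD, n = 5) against −1.87 ± 0.15 (SD, n = 5), and 5 of 5 treated hearts lay above every untreated one (exact permutation p = 0.00794, adjusted p = 0.254 over 32 lists). That p is the smallest 5 against 5 mice can give, so no list could pass this test alone. Neil3, a DNA glycosylase of dividing cells, had a log2 ratio of −0.22 ± 0.28 (SD, n = 5) against −1.97 ± 0.44 (SD, n = 5), a difference of 1.75 ± 0.37 (SE, adjusted p = 0.513).

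In control hearts 0 of 21892 genes passed in limma, with 1036 genes at an unadjusted p under 0.05 where chance gives 1095. A fit of the pair of groups alone, with the spread of these mice only, called 8 genes, Neil3 and Ccnd1, which encodes cyclin D1, among them. In that limma fit 1419 genes had an unadjusted p under 0.05, and the lowest adjusted p was 0.00547. The genes with the smallest p, each at adjusted p = 0.513, also included Tspoap1 (0.98 ± 0.19, SE), the mitotic kinase Melk (1.55 ± 0.35), Ccnd1 (0.92 ± 0.20), Csrp3 (0.48 ± 0.10), a muscle LIM protein, and Plat (0.51 ± 0.12), tissue plasminogen activator. Gramd1b (0.62), the pseudogene Rpl31-ps12 (0.93), Tinf2 (−0.25 ± 0.06) and the predicted gene Gm9548 (0.92 ± 0.17), which passed without treated control 3, belonged to this set as well. Differences were 0.03 ± 0.27 for Fkbp5, 0.16 ± 0.18 for Sgk1, 0.16 for Per1, 0.23 for Tsc22d3, 0.02 for Lcn2, −0.21 for Nr3c2 and 0.88 ± 0.38 for Nppa, each with an adjusted p of 1.00. Ccn2 (0.24), Col1a1 (0.55), Col3a1 (0.55) and Myh7 (−0.38) did not pass either, nor did Nppb (0.93), Serpina3n (−0.01), Nr3c1 (0.09), Hsd11b2 (0.32), Zbtb16 (−0.10) and Myh6 (−0.30).

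Camera called 7 of 32 lists in control hearts, and 0 of their genes passed over all genes tested. Medians were 0.27 for matrix and fibrosis genes (adjusted p = 0.00430, adjusted p = 0.799 with an estimated correlation), 0.12 for hypertrophy genes (adjusted p = 0.0167, 1 rose adjusted over the list alone), 0.12 for fibroblast markers (adjusted p = 0.0198) and 0.19 for macrophage markers (adjusted p = 0.0339). Interferon response genes had a median of −0.21 (adjusted p = 0.00510), and these last 4 lists also had an adjusted p = 0.799 with an estimated correlation. The call of the interferon response list was lost without treated control 1 and without untreated control 2, which scored 0.14 against −1.14 to −0.71 in the other 4. Without control 2 the score difference shrank from −0.23 to −0.01. That of macrophage markers shrank from 0.22 to 0.10 without untreated control 4, and this call was lost in 6 of the 10 fits that left out 1 mouse. Untreated control 2, which scored −0.17 against −1.29 to −0.78 in the other untreated controls, pulled the macrophage difference the other way. Adipocyte markers had a median of −0.51, with 3 lower when adjusted over the list alone (adjusted p = 0.00429, adjusted p = 0.275 with an estimated correlation). Fry called 0 of the 32 lists in this comparison, and leaving out untreated control 1 or treated control 1 left 4 lists. Of 100 assignments of these mice, the real one included, 21 gave as many list calls, so the number of lists called here is not separable from chance.

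In MR-Cardio hearts several genes of mitosis were higher after aldosterone in the fit of all groups. The cell cycle list, given below, was not called by camera with an estimated correlation (adjusted p = 0.123). Pbk, a mitotic kinase, rose 4.36-fold, from −2.03 ± 0.48 (SD, n = 7) to 0.10 ± 0.96 (SD, n = 6; difference 2.12 ± 0.38, SE, adjusted p = 0.00875). Neil3 rose 4.24-fold, Top2a, the topoisomerase of replicating cells, 3.59-fold and Melk 3.47-fold. Lcn2 rose by 1.00 ± 0.21 (adjusted p = 0.0154), a call lost without treated MR-Cardio mouse 4. With aldosterone 314 genes (1.43% of 21892) differed, 208 higher and 106 lower, and 107 differed by 1 log2 unit or more. Without the genes of lowest mean ratio, most cell cycle genes among them, 94 passed (40.4% higher), and 99 (32.3% higher) among genes with a mean ratio over 0. None of the 314 calls was kept with the pair of groups alone in limma, where 0 genes passed and 2562 had an unadjusted p under 0.05 (3109 in the fit of all groups). Leaving out 1 mouse at a time gave 138 to 697 genes, with 146 without MR-Cardio mouse 2, 697 without mouse 5 and 154 without mouse 6, and with 199, 152 and 138 without treated mice 1, 2 and 4.

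The largest rises after aldosterone in MR-Cardio hearts included the spindle checkpoint kinase Bub1 (2.03 ± 0.34, SE), its partner Bub1b (1.74 ± 0.28), the kinetochore proteins Ska1 (1.98) and Kntc1 (1.83), the cohesin acetyltransferase Esco2 (1.71) and Pimreg (1.93). Rbp4, the retinol carrier of plasma, rose by 2.07 ± 0.33, and Rspo4 by 1.99 ± 0.48, a call lost without untreated mouse 1, 2, 3, 6 or 7 and without treated mouse 2, 3, 4 or 6. The largest falls were those of Sun3 (−2.82 ± 0.50), the potassium channel subunit Kcnv2 (−2.31 ± 0.48), Cib3 (−2.31 ± 0.38), Cpxm2 (−1.93 ± 0.35), Fbp2 (−1.85 ± 0.35), the muscle fructose bisphosphatase, and the cadherin Cdh4 (−1.84). Genes fixed in advance that did not pass were Nr3c2 (0.75 ± 0.32, adjusted p = 0.270), Fkbp5 (0.23), Sgk1 (−0.24), Per1 (−0.32), Tsc22d3 (−0.31), Serpina3n (1.00 ± 0.39), Nppa (0.87 ± 0.33), Nppb (1.24 ± 0.51) and Myh7 (1.22 ± 0.47). Col1a1 (0.59), Col3a1 (0.65), Nr3c1 (−0.09), Hsd11b2 (−0.59), Zbtb16 (−0.37) and Myh6 (−0.16) did not pass. Ccn2 differed by 1.80 ± 0.52 (adjusted p = 0.0866) and passed without MR-Cardio mouse 3 or 5.

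Of 24 cell cycle genes 16 rose, 0 fell and 8 did not pass in treated MR-Cardio hearts, and 20 rose adjusted over the list alone, with a median of 0.99 (camera adjusted p = 1.15e-27, adjusted p = 0.123 with an estimated correlation). Without the genes of lowest mean ratio 2 of the 24 are left, with a median of −0.13. Examples were Prc1, which bundles spindle microtubules (1.54 ± 0.23, SE), Bub1b and cyclin A2, Ccna2 (1.46 ± 0.25). The mean ratio of the list was −0.81 ± 0.55 (SD, n = 6) against −1.76 ± 0.20 (SD, n = 7), with 5 of 6 treated hearts above every untreated one (exact permutation p = 0.00350, adjusted p = 0.0497). Of 18 circadian clock genes 5 fell, 0 rose and 13 did not pass (1 rose and 9 fell adjusted over the list alone), among them the clock output factors Tef (−0.60 ± 0.11) and Dbp (−0.98 ± 0.20), with a median of −0.34 (camera adjusted p = 0.00181, adjusted p = 0.153 with an estimated correlation). Of 18 protein breakdown genes 0 rose, 1 fell and 17 did not pass (0 and 7 adjusted over the list alone), with a median of −0.21 (camera adjusted p = 4.42e-05, adjusted p = 0.153 with an estimated correlation). The exact permutation test of scores per mouse called these 3 lists and no other of the 32, and fry called these 3 and the hypertrophy list.

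Of 29 fatty acid oxidation genes 1, Ucp3, a mitochondrial uncoupling protein, fell (−1.14 ± 0.23, SE), 0 rose and 28 did not pass, while 13 fell adjusted over the list alone, with a median of −0.37 (camera adjusted p = 5.75e-11, adjusted p = 0.362 with an estimated correlation). Of 37 oxidative phosphorylation genes none passed either way (0 adjusted over the list alone), with a median of −0.17 (camera adjusted p = 1.00e-05, adjusted p = 0.775 with an estimated correlation), a call lost without treated mouse 1. Of 22 hypertrophy genes 1 rose, Rcan1, a calcineurin regulator (1.22 ± 0.22), and 11 rose adjusted over the list alone, with a median of 0.46 (camera adjusted p = 4.03e-08, adjusted p = 0.193 with an estimated correlation). Of 22 inflammation genes 1 rose, the endothelial selectin Sele (0.81 ± 0.14; 1 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 4.91e-05, adjusted p = 0.368 with an estimated correlation). Of 23 immediate early genes 1 rose (6 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 1.03e-05, adjusted p = 0.265 with an estimated correlation). Of 33 matrix and fibrosis genes 0 passed (5 rose and 1 fell adjusted over the list alone), with a median of 0.49 (camera adjusted p = 4.12e-06, adjusted p = 0.698 with an estimated correlation). None of 14 macrophage markers passed, and their median was 0.25 (camera adjusted p = 0.0232, adjusted p = 0.775 with an estimated correlation), a call lost without untreated mouse 1 or 2 or treated mouse 1 or 5. Without treated mouse 1 the score differences shrank from 0.53 to 0.29 for extracellular matrix and fibrosis, from 0.23 to 0.07 for macrophage markers and from −0.17 to −0.05 for oxidative phosphorylation. This mouse had the highest matrix score of its group, 2.88 against 0.83 to 1.92. Its scores of cardiomyocyte markers (1.48 against 2.08 to 2.23) and endothelial markers (0.95 against 1.39 to 1.65) were the lowest. The untreated mice were split as well. Matrix scores were 0.34 to 0.53 in mice 1, 2 and 6 and 1.35 to 2.03 in mice 3, 4, 5 and 7. Fatty acid oxidation scores were 1.30 to 1.36 and 0.71 to 1.09, and immediate early scores −0.04 to 0.21 and 0.53 to 0.88. Treated scores of 0.83 to 2.88, 0.12 to 0.96 and 0.57 to 0.88 overlapped those of mice 3, 4, 5 and 7. These list differences are thus not separable from the split of untreated mice. As many list calls arose in 57 of 100 assignments of these mice, the real one included.

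**Figure D3:**
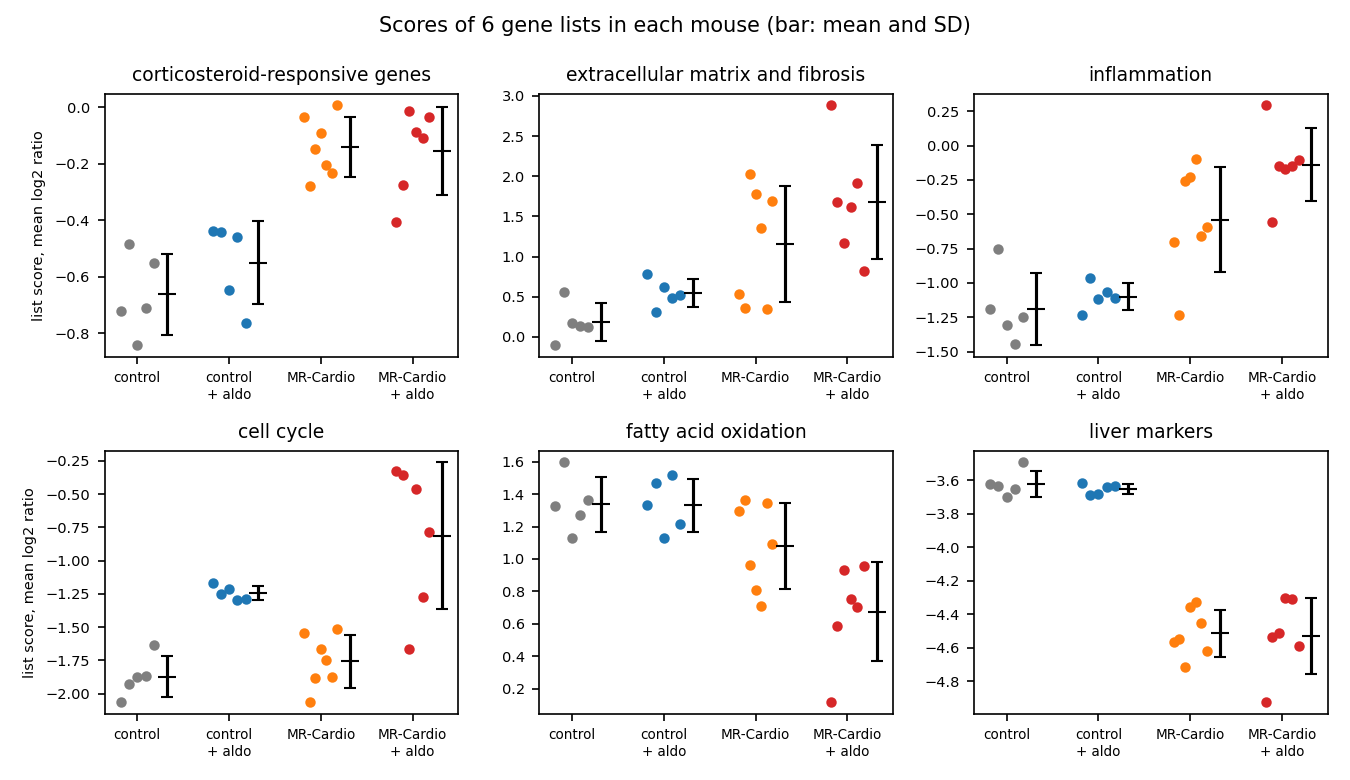
Mean log2 ratio of heart over reference for 6 gene lists in each of the 23 mice, with points for mice and bars for the group mean and SD. Cell cycle scores average −1.24 in treated against −1.87 in untreated controls and −0.81 in treated against −1.76 in untreated MR-Cardio hearts.

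Under aldosterone Nr3c2 was 13.4-fold, Fkbp5 9.89-fold, Lcn2 7.50-fold, Myh7 11.2-fold and Ccn2, a matrix growth factor, 7.68-fold higher in treated MR-Cardio than in treated control hearts (n = 6 and n = 5). Cited1 rose from −0.06 ± 0.16 to 5.62 ± 0.64 (SD), 51.3-fold, and Amy1 rose 70.9-fold. Serpina3n rose by 2.80 ± 0.43 (SE), and Hsd11b2, which inactivates glucocorticoids, fell by 1.08 on the log2 scale (adjusted p = 0.0140). In all, 5487 genes (25.1% of 21892) differed, 2336 higher and 3151 lower, and 1087 of them by 1 log2 unit or more. Ffar4 (40.7-fold), Kcnk1 (33.3-fold), Tnnt3 (31.8-fold) and Mthfd2 (21.8-fold) again rose, and Meig1 (−4.67 ± 0.79), Sun3 (−4.56 ± 0.54), Scn4b (−3.90 ± 0.64), Lgi1 (−3.79) and Cpxm2 (−3.40 ± 0.38) fell. Nr3c1 (−0.19, adjusted p = 0.0292) and Sgk1 (−0.47 ± 0.17, adjusted p = 0.0447) passed narrowly, and both calls were lost with each array centred on its median. Nppa (0.89), Nppb (1.35), Col1a1 (1.45), Col3a1 (1.51), Per1 (−0.43), Tsc22d3 (−0.20), Zbtb16 (−0.19) and Myh6 (0.03) did not pass. The spike-in slope differed by 0.0441 between these groups (exact permutation p = 0.00433), so such an array difference and genotype cannot be told apart here either.

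Inflammation and matrix genes were higher and fatty acid oxidation genes lower in treated MR-Cardio than in treated control hearts. Of 33 matrix and fibrosis genes 19 rose, 0 fell and 14 did not pass (25 and 0 adjusted over the list alone), among them Lox (16.7-fold) and the cytokine Tgfb3 (1.57 ± 0.30, SE), with a median of 1.06 (camera adjusted p = 1.87e-08, adjusted p = 0.497 with an estimated correlation). Of 22 inflammation genes 13 rose, 0 fell and 9 did not pass (13 and 0 adjusted over the list alone), including the cytokine Il6 (13.3-fold), Ptx3 (8.51-fold) and the chemokine Ccl2 (1.42 ± 0.25), with a median of 0.65 (camera adjusted p = 8.04e-08, adjusted p = 0.294 with an estimated correlation). Of 29 fatty acid oxidation genes 18 fell, 0 rose and 11 did not pass (0 and 21 adjusted over the list alone), among them Acot2 (−1.69 ± 0.23) and Ucp3 (−1.68 ± 0.25), with a median of −0.58 (camera adjusted p = 1.49e-07, adjusted p = 0.497 with an estimated correlation). Of 37 oxidative phosphorylation genes 13 fell, 0 rose and 24 did not pass (0 and 16 adjusted over the list alone), with a median of −0.32 (camera adjusted p = 3.65e-05, adjusted p = 0.627 with an estimated correlation). The score difference of oxidative phosphorylation was −0.30, and −0.18 without treated MR-Cardio mouse 1, which scored 0.55 against 1.18 to 1.34 in the other 5. Of 23 immediate early genes 12 rose, 0 fell and 11 did not pass (14 and 0 adjusted over the list alone), including Fosl2 (1.20 ± 0.15), Jund (0.73 ± 0.12) and Atf3 (1.82 ± 0.33), with a median of 0.67 (camera adjusted p = 1.35e-06, adjusted p = 0.294 with an estimated correlation). Of 22 hypertrophy genes 10 rose, 0 fell and 12 did not pass (12 and 1 adjusted over the list alone), including Xirp1 (1.11 ± 0.15) and the intermediate filament Des (1.30 ± 0.20), with a median of 0.76 (camera adjusted p = 3.65e-05, adjusted p = 0.497 with an estimated correlation).

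Of 18 protein breakdown genes 2 rose and 9 fell under aldosterone (2 and 9 adjusted over the list alone), among them the muscle ubiquitin ligase Trim63 (−0.61 ± 0.08, SE) and the autophagy kinase Ulk1 (−0.92 ± 0.13), with a median of −0.23 (camera adjusted p = 0.0330, adjusted p = 0.497 with an estimated correlation), a call lost without treated control 3 or treated MR-Cardio mouse 1. Of 24 cell cycle genes 5 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 0.00123, adjusted p = 0.627 with an estimated correlation). Their scores per mouse (adjusted p = 0.180) and fry (adjusted p = 0.0956) did not pass, and the median was −0.34 without the genes of lowest mean ratio, where 2 of 24 members are left. Of 14 fibroblast markers 5 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 0.00803, adjusted p = 0.567 with an estimated correlation). Of 14 macrophage markers 1 rose, with a median of 0.41 (camera adjusted p = 0.0200, adjusted p = 0.627 with an estimated correlation), a call lost without treated MR-Cardio mouse 1, when the score difference of macrophage markers shrank from 0.39 to 0.23. Their scores per mouse (adjusted p = 0.106) and fry (adjusted p = 0.141) did not pass. All 10 liver markers fell, with a median of −0.83 (camera adjusted p = 6.79e-11, adjusted p = 0.291 with an estimated correlation). Of 11 neutrophil markers 5 fell (5 adjusted over the list alone), with a median of −0.47 (camera adjusted p = 0.0126), and of 7 erythroid markers 2 fell (5 adjusted over the list alone), with a median of −0.38 (camera adjusted p = 0.0330). Both lists had an adjusted p = 0.497 with an estimated correlation, and both calls were lost with each array divided by its spike-in slope. Of 34 corticosteroid-responsive genes 11 rose and 6 fell (12 and 7 adjusted over the list alone), and camera did not call the list (median 0.05, adjusted p = 0.110). Fry called it (adjusted p = 0.0317), and its score was higher by 0.40, with 6 of 6 treated MR-Cardio hearts above every treated control (exact permutation p = 0.00433, adjusted p = 0.0139). Of 34 ion channel and calcium handling genes 5 rose and 10 fell without a list call, including Pln (−1.11 ± 0.18), the inhibitor of the calcium pump Atp2a2 (−0.80 ± 0.15), and Fkbp1b (1.31 ± 0.18). In this comparison 12 of 100 assignments of the mice gave as many list calls.

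The genotype differences of treated and untreated mice, which share no sample, overlapped. Of the genes that rose in untreated MR-Cardio hearts 952 (75.1%) also rose under aldosterone, where independent lists would share 135.2, and 1410 (82.4%) of those that fell also fell, where independent lists would share 246.3. Across genes, which are not independent replicates, the genotype effects correlated with r = 0.797 (Spearman's rho 0.710, jackknife SE 0.0472). The spike-in slope difference between genotypes is common to both comparisons. For the aldosterone effects of the 2 genotypes r was 0.259 (Spearman's rho 0.196, jackknife SE 0.0852). Of the 208 genes that rose with aldosterone in MR-Cardio hearts 192 (92.3%) were also higher in treated controls, and of the 106 that fell 71 (67.0%) were also lower. The median aldosterone effect of all genes in controls was 0.007. Genes of mitosis among the 208 move together, so these shares do not count independent genes.

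No gene's aldosterone effect differed between the genotypes past the threshold. The limma interaction called 0 of 21892 genes, with 1197 at an unadjusted p under 0.05 and a smallest adjusted p of 0.684. The smallest p-values belonged to Gm9548 (−1.16 ± 0.23, SE), Pfkfb2, an enzyme that controls glycolysis (−0.99 ± 0.20), Gramd1b (−0.85 ± 0.18), the lysophosphatidic acid receptor Lpar3 (1.68 ± 0.36) and the clone 4921531C22Rik (−0.58). Lcn2 (0.98 ± 0.31, adjusted p = 0.876), Nr3c2 (0.97, adjusted p = 0.922), Ccn2 (1.56 ± 0.79) and Myh7 (1.59 ± 0.72, adjusted p = 0.901) did not pass. Camera called 9 of 32 lists, among them fatty acid oxidation genes, whose median was −0.37, more negative in MR-Cardio hearts (adjusted p = 1.08e-07), and cell cycle genes, with a median of 0.34 (adjusted p = 0.000396). With an estimated correlation both had an adjusted p = 0.676, fry called 0 lists, and 27 of 100 assignments of the mice gave as many list calls. Genes called with aldosterone in MR-Cardio hearts and not in controls were thus not shown to respond differently in the 2 genotypes.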

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

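Tests of blood cells, of the array of treated MR-Cardio mouse 1, of mislabelled controls and of transgene level were chosen only after the result was seen.

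Liver genes were lower on all arrays of MR-Cardio mice, in both treatments, together with the slope of the spike-in probes, which differed by 0.0479 between untreated and 0.0441 between treated genotypes. A wider ratio scale on these arrays is argued against as the whole cause, since liver genes fell further than genes of the other reference tissues with matched ratios, by −0.523 log2 in the comparison with the smaller gap. Another share of liver RNA in the reference hybridised to these arrays is a candidate explanation: the median of all liver genes was −0.951, the lowest median of another reference tissue was −0.339, and aldosterone within a genotype moved that median by −0.0135 in controls and 0.0062 in MR-Cardio mice. A true difference in liver transcripts of the heart was not tested, and an array difference of this kind cannot be told apart from genotype. Genotype differences of genes that are abundant in liver, and of brain, kidney, spleen and blood genes with their smaller falls (medians of −0.338, −0.339 and −0.318 in untreated mice), may therefore not come from the heart.

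Cell cycle genes were higher after aldosterone in MR-Cardio hearts, and by point values in controls. An array shift that the spike-in offset tracks is argued against, since the median was still 0.922 with the offset as a covariate, and treated MR-Cardio mouse 1 alone is argued against, since the score differed by 0.848 without it. Proliferating blood or immune cells stay open: the highest median of 4 blood and immune lists after aldosterone was 0.249, that of macrophage markers. The score difference of macrophage markers was 0.23 with an SE over mice of 0.220, and it became 0.07 without treated MR-Cardio mouse 1. A response of heart cells to aldosterone, which the design names, is an open and untested explanation of the same values.

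Matrix scores varied more between untreated MR-Cardio mice than between untreated controls. Control hearts labelled as MR-Cardio are argued against, since the lowest Nr3c2 of the untreated MR-Cardio hearts lay 1.94 log2 above the highest control. The spike-in offset stays open: the SD of the matrix score was 2.15 times that of controls with the offset as a covariate and 3.06 times without it, with a range of 1.87 to 3.81 when single mice were left out. Transgene level stays open as well, with 8 of 21 pairs of mice ordered differently by Nr3c2 and by matrix score. A varying course of the heart phenotype between transgenic mice may also contribute and was not tested.

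Of 400 sets of values of 5 to 7 mice examined, 22 held a value far from the others of its set, where chance flags about 1 in 20 sets. Among genes these were, as log2 ratios, 3.39 for Cib3, 0.25 for Ffar4 and 1.31 for Tspan10 in treated control 4, 2.04 for Kcnv2 in treated control 5, −4.23 for Klk1b16 in control 1, and −2.16 for Hamp2 and 0.18 for Nr3c2 in control 3. In untreated MR-Cardio mice they were 0.57 for Gm9548 in mouse 4, 0.29 for Nr3c1 in mouse 2 and −0.91 for Sgk1 in mouse 5. In treated MR-Cardio mice they were 0.58 for Myh6 and 0.33 for Zbtb16 in mouse 1, −6.51 for Dner in mouse 2, −1.06 for Defb19 in mouse 4, and 0.81 for Cpxm2 and −4.37 for Fstl5 in mouse 5. Among list scores they were 1.77 for hypertrophy genes in treated control 1, 0.55 for oxidative phosphorylation genes in treated MR-Cardio mouse 1, 0.16 for interferon response genes and −3.08 for erythroid markers in MR-Cardio mouse 6, −3.86 for neutrophil markers in MR-Cardio mouse 3 and −2.45 for adipocyte markers in MR-Cardio mouse 7.

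Camera's interaction test called 9 lists, fry called 0, none passed with an estimated correlation, and 27 of 100 assignments of the mice gave as many calls, so a difference in aldosterone effect between genotypes is not shown. The median log2 differences were 0.25 for hypertrophy genes (adjusted p = 0.0111), 0.28 for inflammation genes (adjusted p = 0.0111), −0.37 for fatty acid oxidation genes (adjusted p = 1.08e-07), −0.12 for oxidative phosphorylation genes (adjusted p = 0.0133), where the median reversed to 0.00887 without treated MR-Cardio mouse 1, and 0.34 for cell cycle genes (adjusted p = 0.000396), where the median reversed to −0.17 without the genes of lowest mean ratio, with 2 of 24 members left. Immediate early genes had 0.28 (adjusted p = 0.00287), protein breakdown genes −0.18 (adjusted p = 0.00858), lymphocyte markers 0.15 (adjusted p = 0.0262) and adipocyte markers 0.36 (adjusted p = 0.0457), where the median reversed to −0.0548 among genes with a mean ratio over 0. With an estimated correlation the oxidative phosphorylation genes had an adjusted p of 0.877 and the others 0.676.

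Probes without a gene name, which entered no comparison above, also differed between groups. Of 8804 such probes, limma called 765 (8.69%) between untreated genotypes, 37 (0.42%) with aldosterone in MR-Cardio mice and 1283 (14.6%) between treated genotypes.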

How the results depend on the processing

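Spike-in slope scaling, the spike-in offset covariate, genes with a mean ratio over 0 and list scores per mouse were tests chosen only after the results were seen. Of the values of named genes under the alternatives, 7590 kept their direction and side of the threshold, 556 lost and 27 gained a call and 2 reversed. For list shifts the numbers were 3785, 178, 75 and 8. Signal over background is not given in the sources used here, so how dim probes limit these ratios is unknown. Filters on missing and zero values were not run, since there were none, and the interaction has no fit of fewer groups.

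Genes that differed between untreated genotypes (2978) became 1643 with a log2 difference over 0.5, 4806 probes on their own, 1614 without the genes of lowest mean ratio (16419 tested) and 1507 among genes with a mean ratio over 0, with 2199 to 3569 when 1 mouse was left out. Under aldosterone (5487) they became 3137, 8606 probes and 3331 genes with a mean ratio over 0, and 4553 to 5471. For aldosterone in controls (0) the pair of groups alone gave 8 (1419 at an unadjusted p under 0.05 in limma). Leaving out mice gave 0 to 1, with 1 without control 1 and 1 without treated control 3. In MR-Cardio mice (314, 66.2% higher) a threshold of 0.10 gave 680, the pair of groups alone 0 (2562 at an unadjusted p under 0.05 in limma), leaving out the genes of lowest mean ratio 94 (40.4% higher) and a mean ratio over 0 gave 99 (32.3% higher), with 138 to 697 when mice were left out. The filters remove genes by construction, most cell cycle genes among them, and the cause of the other moves was not tested. The interaction had 0 to 1 genes, the latter without treated control 3.

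Lists called numbered 12, 7, 10, 13 and 9 in the order untreated genotypes, aldosterone in controls, aldosterone in MR-Cardio mice, treated genotypes and interaction, and 0 in each with an estimated correlation. Fry gave 0 in controls, 4 in MR-Cardio mice and 0 for the interaction, and scores per mouse gave 0 in controls, where 5 against 5 mice cannot bring a single list past the threshold, and 3 in MR-Cardio mice. Leaving out the genes of lowest mean ratio gave 3 in controls, a mean ratio over 0 gave 3 in controls and 8 between treated genotypes, and quantile normalization gave 5 for the interaction. Leaving out mice gave 10 to 14, 4 to 9, 9 to 11, 10 to 13 and 6 to 11. The correlation of aldosterone effects stayed at 0.217 to 0.287 and that of genotype effects at 0.766 to 0.811.

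Reversals were as follows. With quantile normalization Slc4a1 stood at 0.00345 between untreated and Camp at 0.0933 between treated genotypes. Cell cycle medians were −0.13 for aldosterone in MR-Cardio mice, −0.34 between treated genotypes and −0.17 for the interaction, both without the genes of lowest mean ratio and among genes with a mean ratio over 0, where 2 of 24 members are left. In the interaction adipocyte markers had −0.0548 among genes with a mean ratio over 0, and oxidative phosphorylation genes had 0.00887 without treated MR-Cardio mouse 1, in a range of −0.151 to 0.00887 over the mice left out. The cause was not tested except for the 2 members left.

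With the sample number as a replicate block, genes called for aldosterone in MR-Cardio mice numbered 154 against 314, and the other counts stayed within 1.5 times. Deviations of mice of the same sample number correlated between −0.156 and −0.008 for untreated genotypes, −0.136 and 0.214 for aldosterone in controls, −0.102 and 0.276 in MR-Cardio mice and −0.101 and −0.001 for treated genotypes. A mouse correlated best with that of its own sample number in 0 of 5, 1 of 5, 3 of 6 and 0 of 5 pairs. The numbers are not treated as pairs because the labels do not tie them. For aldosterone in MR-Cardio mice, with 3 of 6 and a count of 154 under the block, these values do not settle the question.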

Other observations

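Gene families outside the fixed lists were chosen after their values were seen. Of 12 measured kallikrein 1 genes, a family of secreted proteases clustered in the mouse genome, 6 rose in untreated and 7 in treated MR-Cardio hearts, with medians of 0.61 and 0.63 and 0 that fell. Klk1b26 rose by 3.63, Klk1b22 by 3.37 and Klk1b5 by 2.77 in untreated hearts, and near-identical copies can share a probe. Of 3 measured amylase genes, digestive enzymes of salivary gland and pancreas, 2 rose in both treatments, Amy1 and Amy2a5, the latter by 3.22 and 4.49. Mean log2 ratios in untreated controls were −4.26 for Amy1, −5.17 for Amy2a5, −4.15 for Klk1b22 and −6.45 for Klk1b5, far below the reference. Klk1b26 stood at −2.05 and Klk1b16 at −0.01. Another make-up of the reference RNA could also move such low ratios, which was not tested. These rises cannot be told apart from an array difference that follows genotype. Of 12 skeletal muscle markers, a list fixed in advance, Myh2, also chosen after its values were seen, rose by 1.43 in untreated MR-Cardio hearts besides the troponins Tnnt3 and Tnni2, while the fast calcium pump Atp2a1 and the myogenic factor Myod1 fell, each by 0.84 on the log2 scale.

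Other assignments of the mice to groups of the same sizes were fitted to ask whether chance can be excluded, with 100 assignments per result, the real one included. For genes between untreated genotypes 1 gave a count as large (2978 real, 1665 the highest other), and between treated genotypes 1 (5487 and 4). Chance is thus excluded at 0.05 for these 2 counts, without adjustment over the results examined. The spike-in slope separates the arrays of the genotypes in the same way, so these counts do not tell genotype from an array difference. For aldosterone in MR-Cardio mice 2 assignments reached the real count (314 real, 364 the highest other). With the pair of groups alone 0 genes passed there and leaving out mice gave 138 to 697, so chance is not excluded for that count. For aldosterone in controls and for the interaction all 100 reached the real count of 0, as any must, so this says nothing of chance. The highest others were 886 and 295 with a median of 0, and calls of that number may point to a structure of the samples, which was not tested. For list calls 5 (12 real, 12 the highest other), 21 (7 and 10), 57 (10 and 15), 12 (13 and 14) and 27 (9 and 14) gave as many, in the order untreated genotypes, aldosterone in controls, aldosterone in MR-Cardio mice, treated genotypes and interaction, and chance is not excluded for any of them. Medians of the other assignments were 7, 4, 10, 9 and 6 lists, in the same order. The correlations of aldosterone effects (0.259 real, 0.198 the highest other) and of genotype effects (0.797 and 0.492) were reached by 1 assignment each, the real one.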
